A study of Homo sapiens with 4 samples.

How the data were processed

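RNA from HTR-8 cells was sequenced in 4 libraries, 2 with a control small interfering RNA and 2 with one against TET, which the series description gives as TET3. Groups and replicate numbers come from the sample titles. Total RNA went into an mRNA library kit, per the labels' protocols. The authors deposited 1 table of gene counts and 1 of FPKM values. The reads were processed with STAR, StringTie and DESeq2 on hg38, per the submitters' processing notes, with versions and settings not given in the sources used here. The deposited counts are whole numbers, not normalized. The deposited FPKM values are scaled by the authors to transcript length and library size. Whether counting used strand is not given in the sources used here, so antisense and overlapping genes are uncertain.

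The count table had 60737 rows for 60605 gene IDs. Of these IDs, 44 stood on 4 rows each, with every distinct row repeated, and their rows were summed and halved. No count was found in any library for 22554 genes. Total counts ran from 105885173 to 161180460 per library. Replicates of a group were compared by a chi-square test over genes, which gave 15.7 per degree of freedom for the controls and 63.4 for siTET, so no library was a copy of another. Mitochondrial genes took 2.03% and 1.85% of control counts and 2.23% and 1.74% of siTET counts.

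Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (18898 genes), scaled by TMM and fitted by quasi-likelihood with group as the only term. P-values were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. CPM values use TMM-scaled library sizes. Named genes were TET3, TET1 and TET2, then the 10 genes higher and 10 lower with the smallest p among those at 5 CPM or more on average whose siTET libraries both lay on 1 side of both controls, and up to 2 members of each passing list by highest expression. The rule, the gene lists and the tests were fixed before the data were examined. Any other gene named was chosen after its values were seen. Of 42 lists, 40 had at least 5 tested members, and the endothelial and germline lists, with fewer, were not tested. Lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 on log-CPM with a prior count of 2. Median, mean and camera direction differed in sign for 9 lists.

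Gene positions and exon overlaps come from GENCODE on GRCh38, which held 58337 of the gene IDs. Alternatives were other scalings (RLE, library sizes only), filters on low counts, DESeq2 1.42.0, limma-voom, limma on log2 FPKM with pseudocounts of 1 and 0.1, a replicate block, equal depth by thinning, and leaving out each library. Robust dispersions and a restriction to coding genes at 5 CPM or more were added after seeing the data.

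The tests were checked on simulated data drawn with the means, library sizes and gene-wise dispersions of these libraries, with 200 of 18898 genes changed. The edgeR test found 62.7% of genes changed by a fold of 1.5, 98.5% at a fold of 2 and 100% at a fold of 4. In that simulation 26 of its 200 calls (13%) were genes that had not been changed, more than the nominal rate. These shares of genes found may not hold for the measured libraries. There STBD1 (log2 fold change −1.86, edgeR adjusted p = 0.0826) and PRORP (1.05, edgeR adjusted p = 0.313) did not pass. A lack of calls thus does not show that no gene changed by a fold of 2. A list shifted by 0.5 on the log2 scale was called by camera, and 0 lists were called in the only draw examined with no shift. Genes were drawn independently of each other. The check therefore cannot show how often correlation between members leads to a list call.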

Results

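RNA was measured by sequencing in HTR-8 cells, an immortalised trophoblast line grown out of first-trimester placenta. The cells had received either a control small interfering RNA or one against TET, called siTET here. The sample titles name TET alone, and the series description gives TET3 as the gene depleted. TET3 encodes a dioxygenase that oxidises 5-methylcytosine in DNA. Each group had 2 libraries, numbered replicate 1 and replicate 3. The total counts were 134105140 and 105885173 in control replicates 1 and 3, and 153277351 and 161180460 in siTET replicates 1 and 3. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. With 2 libraries against 2, the smallest two-sided exact permutation p for a single value is 0.333, and tests that share the spread across genes were used.

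The comparison asks what changes in these cells when TET3 is targeted. TET3 itself (ENSG00000187605, GRCh38 chromosome 2, 73986404 to 74108176, plus strand) was at 21.7 and 22.1 CPM (read counts scaled to library size) in the control libraries. It was at 18.2 CPM in siTET replicate 1 and 14.1 CPM in siTET replicate 3. The group means were 21.9 ± 0.267 CPM in control and 16.2 ± 2.92 CPM in siTET (SD, n = 2 each), so the siTET mean stood at 73.9% of the control mean. Both siTET libraries lay below both controls. The log2 fold change was −0.44 (SE 0.13, 95% interval −0.76 to −0.11), which did not pass the threshold over all genes (adjusted p = 0.783, edgeR quasi-likelihood test). Adjusted over the list alone, for the 18 TET and DNA methylation enzymes, TET3 had an adjusted p of 0.323 by the same edgeR test. Without siTET replicate 1 the TET3 change was −0.63 (edgeR adjusted p = 0.0342), and without siTET replicate 3 it was −0.26 (edgeR adjusted p = 0.682). In both of these fits the lone siTET library is assumed to vary like the controls.

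The 2 related dioxygenases did not differ beyond the spread between replicates. TET1 (chromosome 10, 68560656 to 68694482) was at 2.57 and 1.84 CPM in control and at 2.59 and 2.66 CPM in siTET, with a log2 fold change of 0.25 (SE 0.20, edgeR adjusted p = 0.831). The TET1 value was 0.515 without control replicate 1 and 0.0336 without control replicate 3. TET2 (chromosome 4, 105145875 to 105279816) was at 14.8 and 14.02 CPM in control and at 15.2 and 13.3 CPM in siTET. Its log2 fold change was −0.01 (SE 0.095, edgeR adjusted p = 0.982), and its sign turned under several alternatives.

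**Figure D1:**
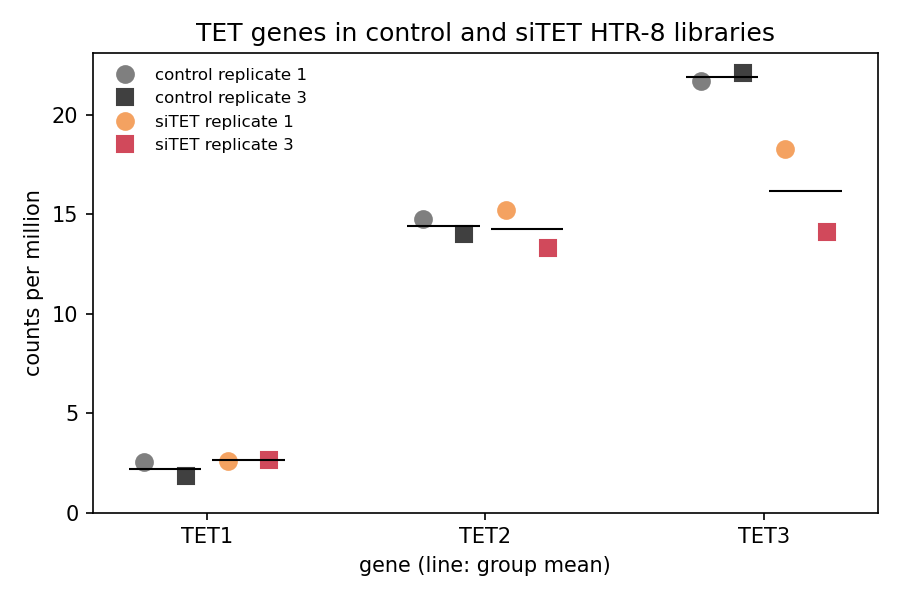
CPM (vertical axis) of TET1, TET2 and TET3 (horizontal axis) in each of the 4 libraries, with a line at each group's mean. For TET3 the siTET libraries sit at 18.2 and 14.1, below the controls at 21.7 and 22.1, while TET1 and TET2 overlap or lie close together.

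Across 18898 tested genes, no gene was higher and none was lower in siTET at an adjusted p under 0.05 by edgeR. At an unadjusted p under 0.05 there were 1157 genes, 560 higher and 597 lower, where 945 are expected by chance. DESeq2, which tested 21613 genes, called 35 higher and 37 lower on the same counts, and limma-voom called 0. Of the 72 DESeq2 calls, 22 were under 1 CPM on average. Without siTET replicate 1, edgeR called 128 genes higher and 120 lower, a fit in which the lone siTET library is assumed to vary like the controls. In 20 simulations with no change, that 3-library fit called between 2 and 106 genes, so its count is not held to the nominal error rate. The 4-library fit called between 0 and 14 genes in the same simulations. Without control replicate 1 edgeR called 5 genes higher and 1 lower, and without siTET replicate 3 it called 2 and 4. Among 9145 coding genes at 5 CPM or more, 3891 (42.5%) had both siTET libraries on 1 side of both controls, where chance gives 33.3%.

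The genes with the smallest p-values are given as values, since none passed the edgeR threshold. Among those higher in siTET, NOLC1, a nucleolar phosphoprotein, was at 1061 and 1041 CPM in control and 1299 and 1315 CPM in siTET (log2 fold change 0.32, SE 0.043). POLR1G, a subunit of RNA polymerase I, was at 179 and 135 CPM in control and 254.5 and 271 CPM in siTET (log2 fold change 0.75). OGFR, the opioid growth factor receptor, had a log2 fold change of 0.40, R3HCC1 of 0.26 and MYO18A, an unconventional myosin, of 0.23. In log2 FPKM with a pseudocount of 1 the R3HCC1 value was 0.105, and control replicate 3 lay above both siTET libraries. Among those lower in siTET, GLO1, the glyoxalase that detoxifies methylglyoxal, was at 90.1 and 91.1 CPM in control and 75.3 and 72.7 CPM in siTET (log2 fold change −0.29). TWF1, an actin monomer-binding protein, had a log2 fold change of −0.32 and SREK1IP1 of −0.30. In log2 FPKM with a pseudocount of 1 the TWF1 value was −0.151, and siTET replicate 1 lay above control replicate 1. SPOUT1 was at 61.2 and 62.5 CPM in control and 33.2 and 35.7 CPM in siTET (log2 fold change −0.85, SE 0.059, edgeR adjusted p = 0.0826). The edgeR adjusted p-values of the 20 genes named by smallest p ran from 0.0563 to 0.783. DESeq2 put 18 of the 20 past its threshold.

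Of the genes given so far, MYO18A shares exons with TIAF1. The remaining named genes share exons with a neighbour or were not found in the annotation used. RP11-561B11.2 (chromosome 14, 35122549 to 35317474) runs across PRORP, a mitochondrial RNase P subunit, and PSMA6, a proteasome subunit. It was at 109 and 81.9 CPM in control and 2.50 and 4.92 CPM in siTET, a log2 fold change of −4.69 (SE 0.35). PRORP was at 20.3 and 25.2 CPM in control and 46.0 and 48.5 CPM in siTET, and PSMA6 at 160 and 173 CPM against 218 and 233 CPM. The sum over the 3 gene models was 289.5 and 279.7 CPM in control and 266.1 and 286 CPM in siTET. STBD1, a glycogen-binding protein whose exons overlap FAM47E-STBD1, was at 9.05 and 8.76 CPM in control and 2.28 and 2.62 CPM in siTET. RP11-6N17.9 (2.19), HNRNPUL2-BSCL2 (1.45), AC005943.2 (−1.63), RP5-940J5.10 (−1.85) and AARSD1 (−0.53), with log2 fold changes in parentheses, also lie in overlapping models. The gene ENSG00000286112 had a log2 fold change of 1.21 (edgeR adjusted p = 0.0563) and CH17-159N18.5 of −1.22, and neither was in the annotation used. Counts of overlapping models are uncertain, because the division of reads between them was made in the deposited table.

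**Figure D2:**
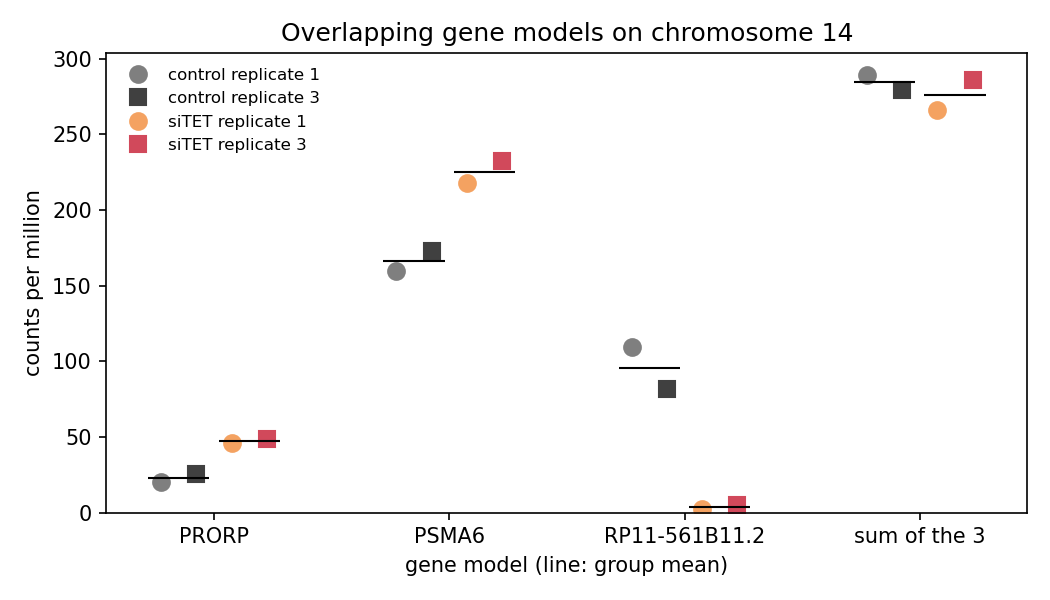
CPM (vertical axis) of PRORP, PSMA6, RP11-561B11.2 and their sum (horizontal axis) in each library, with lines at the group means. RP11-561B11.2 is at 109 and 81.9 in control and 2.50 and 4.92 in siTET, while the sum lies between 266.1 and 289.5 in the 4 libraries.

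Of 40 gene lists fixed in advance, 3 passed the camera test with a preset correlation, and no list held a member past the threshold, over all genes or adjusted over the list alone. The integrins, cell surface receptors for extracellular matrix, were lower in siTET (14 tested, 11 below 0, median log2 fold change −0.22, camera adjusted p = 0.0212). The integrins did not pass with an estimated correlation (adjusted p = 0.882) or without siTET replicate 3 (camera adjusted p = 0.16). ITGB1 was at 1038 and 985 CPM in control and 908 and 894 CPM in siTET, and ITGA3 at 216 and 221 CPM against 215 and 222 CPM. Targets of NRF2, the regulator of antioxidant genes, were higher (16 tested, 14 above 0, median 0.28, camera adjusted p = 0.0242). The NRF2 list did not pass with an estimated correlation (adjusted p = 0.882), and without siTET replicate 3 its camera adjusted p was 0.399. TXNRD1, a thioredoxin reductase, was at 895, 876 and 894 CPM in both controls and siTET replicate 1, and at 1577 CPM in siTET replicate 3. PGD was at 295 and 291 CPM in control and 289 and 286 CPM in siTET. Markers of immune cells were higher (6 tested, 5 above 0, median 0.69, camera adjusted p = 0.0242). This list too was lost with an estimated correlation (adjusted p = 0.882) and without siTET replicate 3 (camera adjusted p = 0.16). Apart from CD68, a lysosomal protein at 153 and 134 CPM in control and 157 and 185 CPM in siTET, these markers were near the floor, with PTPRC at 0.715 and 0.528 CPM in control and 0.914 and 0.856 CPM in siTET. By fry, 0 lists passed. The immune markers had an estimated correlation of −0.0212, below the preset 0.01. Their loss in that setting thus does not come from correlation between members. For the NRF2 targets the estimated correlation was 0.374 and for the integrins 0.0696, both above the preset 0.01. The camera adjusted p of these lists at the preset value may therefore be too small. With 4 libraries the test with an estimated correlation has little power, so a list lost there is not shown to be unchanged.

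The siTET libraries differed from each other. The spread of log2 differences over 9145 coding genes (median absolute deviation, scaled to match an SD) was 0.0845 between the controls and 0.134 between the siTET libraries. It was 0.108 and 0.104 between siTET replicate 1 and controls 1 and 3, and 0.157 and 0.149 for siTET replicate 3. By SD, siTET replicate 1 was about as close to the controls (0.198 and 0.202) as they were to each other (0.209). For siTET replicate 3 the SD values were 0.265 and 0.275. The NRF2 targets had a median of 0.05 in siTET replicate 1 and 0.44 in replicate 3, against the control mean. The replication-dependent histones, fixed as a sign of RNA quality, had medians of 0.02 and −0.50. This list was near the floor, with a median expression of 0.583 CPM over its members. H1-2, far above that level, was at 12.9 and 12.4 CPM in control and 12.8 and 11.8 CPM in siTET. Fibroblast and stromal markers had medians of 0.06 and −0.31, and the mitochondrially encoded genes 0.25 and −0.13. Markers of villous cytotrophoblast, the progenitor cells of the placental epithelium, had a median of 0.02 in siTET replicate 1 and −0.36 in replicate 3. Of 16 such markers 12 were tested, since ELF5, CDX2, PAGE4 and VGLL1 had too few counts, so these medians cover only part of the list. Immediate early and AP-1 genes, which respond fast to stimulation, had medians of 0.00 and 0.41. Without siTET replicate 1, 8 lists passed camera. Villous cytotrophoblast markers (adjusted p = 0.000189), fibroblast and stromal markers, collagens, histones and integrins were lower, and immediate early and AP-1 genes (adjusted p = 0.00053), NRF2 targets and immune markers were higher. These calls use the preset correlation of 0.01. Over the 4 libraries the estimated correlation was 0.559 for fibroblast and stromal, 0.395 for villous cytotrophoblast and −0.0212 for immune markers. It was 0.374 for NRF2 targets, 0.304 for histones, 0.275 for collagens, 0.113 for immediate early genes and 0.0696 for integrins. Except for the immune markers, the adjusted p at the preset value may thus be too small. Some of these lists share members, such as the collagen and fibroblast lists. In the 4-library test with an estimated correlation, which has little power here, the same lists had adjusted p from 0.882 to 0.988. Without siTET replicate 3 the mitochondrially encoded genes alone passed (camera adjusted p = 0.0289). Over the 4 libraries their estimated correlation was 0.914, far above the preset 0.01, and with it their adjusted p was 0.988. Without control replicate 1 the immune markers alone passed (camera adjusted p = 0.0222), with integrins and NRF2 targets each at 0.278, and without control replicate 3, 0 lists passed. Lists of the cell cycle, interferon response and glycolysis did not pass: the medians were −0.02 for mitosis, 0.08 for interferon-stimulated genes and 0.02 for glycolysis. The lists of imprinted genes (median 0.04) and HOX genes (median −0.05) did not pass either.

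**Figure D3:**
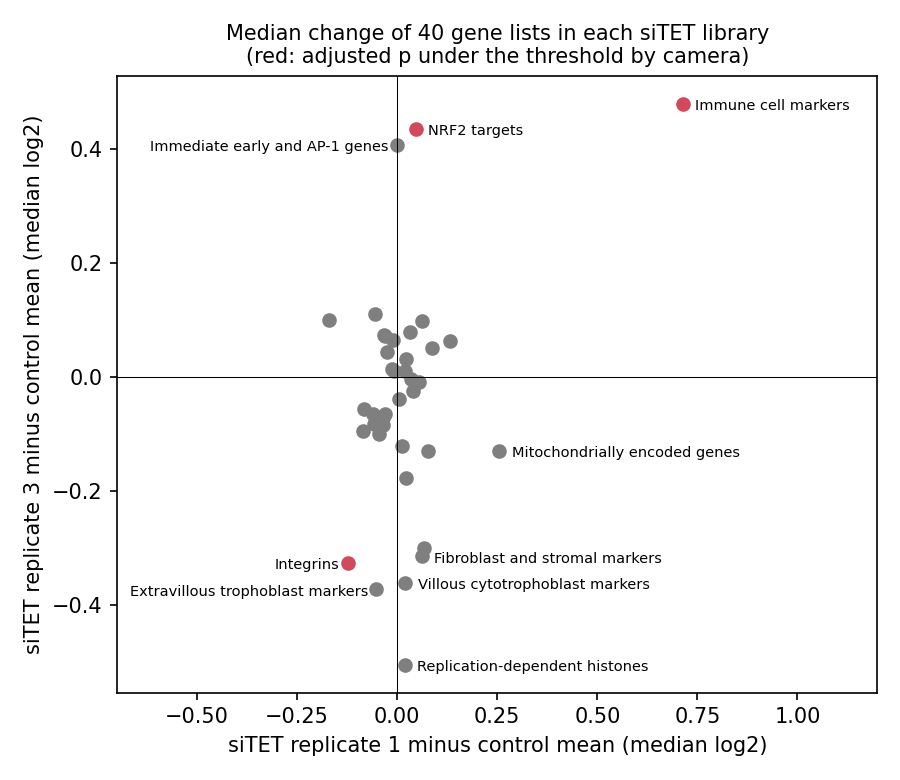
Median log2 difference from the control mean over each of 40 gene lists, in siTET replicate 1 (horizontal axis) and siTET replicate 3 (vertical axis), with lists that pass camera in red. NRF2 targets lie at 0.05 and 0.44 and replication-dependent histones at 0.02 and −0.50, and in 30 of 40 lists the median is farther from 0 in replicate 3.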

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

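Robust dispersions and the restriction to coding genes were chosen after seeing the data; all other alternatives were planned. No gene passed in the main edgeR fit, and the counts of genes higher and lower stayed at 0 with RLE scaling, no filter, limma-voom, both FPKM scales, a change of at least 1 on the log2 scale and the replicate block. Library sizes only and a mean of at least 5 CPM each gave 1 higher and 0 lower, thinning gave 2 and 0, robust dispersions 4 and 3, coding genes at 5 CPM or more 1 and 3, and DESeq2 35 and 37. Leaving out 1 library gave 0 to 128 higher and 0 to 120 lower, with the highest counts without siTET replicate 1, where the lone siTET library is assumed to vary like the controls. The cause of these differences was not tested.

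TET3 stayed below control in 16 of 16 alternatives. Its smallest change was −0.238, on the FPKM scale with a pseudocount of 1, and it was −0.393 there with a pseudocount of 0.1. Leave-one-out values ran from −0.632 to −0.263, and the adjusted p (edgeR, DESeq2 or limma) from 0.0342 without siTET replicate 1, the only alternative past the threshold, to 0.999. The replicate block gave −0.448; the replicate numbers do not pair the libraries by the labels, and the correlation of deviations was −0.0108. TET2, at −0.01, turned to 0.00526 with no filter, 0.00875 and 0.012 on the FPKM scales with pseudocounts of 1 and 0.1, and 0.00197 after thinning; leave-one-out values ran from −0.116 to 0.0806. Leave-one-out values of TET1 ran from 0.0336 to 0.515. The 20 other named genes kept their direction in 319 of 319 values. Their choice largely fixed this, since both siTET libraries had to lie on 1 side of both controls.

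Of the gene lists, 3 passed in the main test, 0 with an estimated correlation (a test with little power here) and 0 by fry. The count was 4 with the replicate block and 3 with RLE or a prior count of 0.5. Leaving out 1 library gave 0 to 8. The other 2 ways of splitting the libraries into pairs called 0 and 4 genes, too few splits to judge chance. The shallowest library held 105885173 counts, and replicates differed by more than counting error (chi-square per degree of freedom 15.7 in control and 63.4 in siTET).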

Other observations

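The genes, tests and explanations in this part were chosen after the values were seen. ANKRD1, a target of the YAP coactivator, was at 13.9 and 10.98 CPM in control, 8.81 CPM in siTET replicate 1 and 110 CPM in siTET replicate 3. CCN2, another such target, was at 21.4, 21.5, 16.6 and 44.6 CPM in the same order, and F3, tissue factor, at 26.2, 27.7, 24.3 and 67.7 CPM. The list of YAP and TEAD targets that holds these 3 genes did not pass as a whole: in siTET replicate 3, 7 of 16 members were above the control mean with a median of −0.08, and without siTET replicate 1 its camera adjusted p was 0.825. FN1, fibronectin, was at 509 CPM in each control, 536 CPM in siTET replicate 1 and 283 CPM in siTET replicate 3. COL3A1, a fibrillar collagen, moved apart in the siTET libraries, with 41.1 and 40.3 CPM in control, 65.9 CPM in replicate 1 and 11.95 CPM in replicate 3. FTL, the ferritin light chain, was at 177 and 182 CPM in control, 191 CPM in replicate 1 and 342 CPM in replicate 3.

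These values raise the question of why siTET replicate 3 stands apart. A smooth trend on GC content and transcript length took 2.7% of the variance of its deviation from the controls over 9546 genes. This small share argues against that trend. Over the called genes the trend was at a median of 0.028 against a change of 0.61, but these genes were chosen by that change. The library pairs argue against depth as the only source, though each group gives only 1 pair. The siTET libraries also differ in TET3 level, so a contribution of depth is not excluded. The siTET libraries were 5.2% apart in depth and the controls 26.7%. Yet log2 differences spread 1.58 times as widely between the siTET libraries (95% bootstrap interval over genes 1.53 to 1.63). That interval does not measure how library pairs vary. By SD the gap was smaller, at 0.243 between the siTET libraries and 0.209 between the controls. A response graded by TET3 would put replicate 1 at about 0.415 of the replicate 3 change, the ratio of their TET3 changes. Over the 40 preset lists, with each siTET library set against a different control, the slope was 0.17 (95% bootstrap interval over lists −0.13 to 0.53; −0.039 without the immune markers), so a graded response and no relation cannot be told apart. A response that begins only below some TET3 level, a difference in culture or handling, and a library effect stay open and were not tested.

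Call counts were a poor measure for tests of depth and of the trend. Thinning to equal depth, which keeps the ratios between libraries on average, kept all 248 genes but raised the calls without siTET replicate 1 to 417, and removing the trend from each library, which moved only 21 genes by over 0.1, raised them from 243 to 622. A criterion based on the share of genes still called was tried first and set aside for this reason. The ratio of the siTET replicate 1 to the replicate 3 change over the 211 called genes at 5 CPM or more (median 0.018) was set aside too, since choosing genes by replicate 3 pulls it toward 0. So were 2 further tests: the share of the change left after removing the trend, which a small trend fixes near 1, and the list slope as a test of depth, which left depth open.

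Many genes with the smallest p-values share exons with another gene model. Of the 20 named genes, 18 were in the annotation and 10 of these overlapped, in 8 loci, since PRORP, PSMA6 and RP11-561B11.2 form 1. Counted by locus, 8 of 16 (50%) overlapped, against 15.2% of 9302 loci of tested genes at 5 CPM or more (Fisher's exact test, two-sided p = 0.00115). Reads assigned to a different one of several overlapping models may account for part of this. Over the 6 loci whose sum varied less between replicates than the named gene changed, the sum changed by a median of 0.258 of the gene's own change in CPM. In 5 of the 6 the ratio was at most 0.5. The exception was MYO18A, where it was 1.01 and its neighbour TIAF1 changed by only 0.306 CPM. The loci left out by this rule, those of AC005943.2 and RP5-940J5.10, had ratios of 0.349 and 17.1. A first version of this test compared log2 changes and was set aside because an abundant neighbour hides any change of a rare gene. A real shift in the use of these transcripts in siTET cells and a difference in how the libraries were assembled stay open and were not tested.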
